A study of Mus musculus with 12 samples.

How the data were processed

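Liver RNA of 12 mice was measured on Affymetrix arrays, 3 animals in each of 4 groups (untreated and MMS-treated wild type, untreated and MMS-treated Aag knock-out). Total RNA was extracted with Trizol and made into biotin-labelled cRNA, per the labels' protocols. The deposited table holds 1 log2 expression value per probe set and array. The values were made with RMA, a method of background correction, normalization and probe set summary, per the submitters' processing notes. Its version, the chip definition used and which arrays were normalized together are not given in the sources used here. The log base is not written in the table and was taken from the usual output of RMA and from the range of the values. Array medians were close but not identical, so the table as a whole is not quantile-normalized. Such processing sets the arrays to a common scale, so a change shared by most genes would not be seen, and the balance of higher and lower calls moves with the scaling. No background or detection call came with the values, so dim probe sets could not be told from absent ones.

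Samples were assigned to groups from the labels, and each column was matched to its sample by name. The table had 0 extra sample columns. It holds 22690 probe sets, of which 64 control probe sets were set aside and 22626 tested. Probe sets were named through the platform annotation: 20380 had 1 gene symbol, 691 had several and 1555 had none, and 20351 symbols were updated through the gene identifier in a RefSeq gene table (GRCm38.p6), which was used only for names, gene lengths and neighbours. No gene was named from a probe set with several symbols. Each of 12393 genes was represented by its probe set with the highest mean over the 12 arrays. Other probe sets of a gene were left out of the gene lists and of the named values, and for genes past the threshold the text says where one of them had the opposite sign.

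All tests used limma 3.58.1 in R 4.3.3, with 1 mean per group fitted to the 12 arrays (8 residual degrees of freedom), moderated variances, and Benjamini-Hochberg adjustment over the 22626 probe sets at a threshold of 0.05. The 5 contrasts were the MMS response in each genotype, the genotype difference without and with MMS, and the difference of the responses. A total of 38 gene lists, covering stress and repair pathways, metabolism and markers of liver and other cell types, were fixed before the data were examined, as were the contrasts, the rule for named genes and most of the other settings tried. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and the rotation test fry as alternatives. Lists not mentioned for a contrast were not called there by camera, and fry also called 2 other lists in the wild-type response (erythroid markers and drug metabolism, adjusted p = 0.0286 and 0.0412, both lower) and 1 in the knock-out response and between treated genotypes (cholangiocyte markers, adjusted p = 0.0396 and 0.0238, both higher). For the targeted gene an exact two-sided permutation test within treatments was added.

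Named genes were Mpg, then for each contrast and direction the 10 with the largest change among genes past the threshold whose groups did not overlap, or the 3 with the smallest p if none passed. For each list described, up to 4 members with the smallest p were named, and members past the threshold could be added. Not every gene that the rule names is printed in the text. Replicates are separate animals by their titles. The animal numbers are shared between groups but nothing in the labels says that they mark a litter, day or batch, and no scan date or other batch was given.

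The fit was tested on simulated data before use. The simulation changed 50 probe sets per size among 22626 in the wild-type MMS response, with the spread of the fit to all 12 arrays. The fit recovered 45 of those lowered by 2 on the log2 scale, 30 lowered by 1, 28 raised by 1 and 50 raised by 2, with 3 false calls among 156 (1.92%). It made 0 calls in an unchanged comparison. In a simulation of 12393 genes a shift of 0.5 in the proteasome list was recovered and 0 other lists were called. The simulated noise was independent between genes and held no structure among arrays, so these error rates do not carry over to the real arrays. Other splits of the real arrays called up to 16 lists and up to 875 probe sets. Other settings chosen before the values were seen were 2 filters on low values, a further quantile normalization, median centring, a trended robust variance, array weights, the animal number as a block, leaving out each array in turn, 1 probe set per gene or the mean of a gene's probe sets, the spread of the compared groups alone and a model without moderation. A pseudocount was not run, since the values are log2. Chosen after seeing the data were the fits without both knock-out arrays numbered 3, with the 5' to 3' signal of control probe sets as a covariate and with a clock score as a covariate.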

Results

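Gene expression was measured in the livers of 12 mice on 1-colour Affymetrix arrays, with 1 array per animal. The mice were C57Bl/6J, 6 to 8 weeks old, and either wild type or lacking Aag, also named Mpg, the glycosylase that removes alkylated bases from DNA at the start of base excision repair. In each genotype 3 mice had received methyl methanesulfonate (MMS), a DNA-methylating agent, as 1 intraperitoneal dose of 75 mg/kg with the liver taken 6 hours later, and 3 were controls, called untreated here. Whether the controls received an injection, and the time of day at collection, are not given in the sources used here. The deposited log2 values had array medians of 7.42 to 7.75, and pairs of arrays correlated at 0.962 to 0.995 across probe sets. For 9 of the 12 arrays the closest other array came from the same group. The exceptions were MMS-treated knock-out array 3, closest to untreated wild-type array 2 (r = 0.989), MMS-treated wild-type array 1, closest to untreated knock-out array 2 (r = 0.989), and untreated knock-out array 3, closest to MMS-treated knock-out array 3 (r = 0.987). Changes are log2 differences with the standard error of the fit, and each group holds 3 arrays. That number limits the precision of every value below.

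At 1 of its 2 probe sets, Mpg was lower in every knock-out array than in every wild-type array. The log2 values were 6.43 ± 0.20 in untreated and 6.72 ± 0.28 in treated wild-type liver, against 5.33 ± 0.34 in untreated and 5.47 ± 0.24 in treated knock-out liver (mean ± SD, n = 3 each). The lowest wild-type value was 6.21 and the highest knock-out value 5.75. Within treatments the knock-out was 2.25-fold lower (log2 difference -1.17), with an exact two-sided permutation p of 0.005 over 400 regroupings, the smallest they can give. In the fit over all probe sets the genotype differences at this probe set, -1.10 ± 0.21 without treatment and -1.24 ± 0.21 after MMS, did not pass the limma threshold (adjusted p = 0.356 and 0.0793). The other Mpg probe set had overlapping values (log2 difference -0.31, exact permutation p = 0.04). Where either probe set lies relative to the deleted part of the gene is not known here, so the transcript that remains is not interpreted.

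The wild-type comparison asked which transcripts differ 6 hours after MMS when Aag is present, with the unfolded protein response, the gene programme induced by misfolded proteins in the endoplasmic reticulum, among the processes of interest. Creld2, an endoplasmic reticulum protein induced by folding stress, rose by 2.27 ± 0.35 (4.82-fold, adjusted p = 0.00711), and Syvn1, the ubiquitin ligase that marks misfolded proteins for degradation, rose by 1.90 ± 0.35. Manf, a secreted stress-induced factor, rose by 1.26 ± 0.27 and Hspa5, the main chaperone of the compartment, by 0.62 ± 0.15. Of 35 measured chaperone and degradation genes 8 rose, none fell and 27 were not called, and 11 rose when adjusted over the list alone. The list had a camera adjusted p of 4.3e-07, and adjusted p = 0.470 with an estimated correlation. Of 32 targets of PERK and ATF4, the branch that answers such stress through translation control, 6 rose, 1 fell and 25 were not called, with 10 higher and 1 lower adjusted over the list alone. These included Nupr1, a stress-induced chromatin protein (2.10 ± 0.29), and Trib3, a pseudokinase (1.86 ± 0.45). Also risen were Atf3, a stress transcription factor (0.95 ± 0.21), and Wars, a tRNA synthetase (0.85 ± 0.13). Ddit4, an inhibitor of growth signalling, fell by 1.16 ± 0.31. This list passed with the preset correlation (camera adjusted p = 4.5e-07) and with an estimated correlation (adjusted p = 0.0473).

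Acute phase genes, which the liver switches on in inflammation, were the list with the smallest p in wild-type liver. Of 28 measured members 10 rose, none fell and 18 were not called, and 16 rose when adjusted over the list alone (camera adjusted p = 3.0e-09, adjusted p = 0.470 with an estimated correlation). The metallothioneins Mt2 and Mt1, which bind metal ions, rose by 4.23 ± 0.62 (18.7-fold) and 2.32 ± 0.42, Orm2, a secreted plasma protein, by 2.80 ± 0.63 and Saa2, a serum amyloid, by 2.41 ± 0.53. In the list of NF-kB and cytokine genes 3 of 25 rose, none fell and 22 were not called, with 4 higher adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.479 with an estimated correlation). They were Cxcl1, a chemokine that attracts neutrophils (3.96 ± 0.86), Icam1, a leukocyte adhesion molecule (1.45 ± 0.15), and Bcl3, a regulator of NF-kB (1.14 ± 0.28). The neutrophil marker list was not called (camera adjusted p = 0.303), although its members S100a9 and S100a8 rose by 2.62 ± 0.57 and 2.33 ± 0.44. Of 26 ribosome biogenesis genes 3 rose, none fell and 23 were not called, with 4 higher adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.479 with an estimated correlation). They included Gnl3, a nucleolar GTPase (0.94 ± 0.18). The proteasome list was called higher with 0 of 31 members past the threshold in limma, 0 adjusted over the list alone and 23 positive (camera adjusted p = 0.00451, adjusted p = 0.479 with an estimated correlation). Its member with the smallest p, Psmc6, stood at 0.28 ± 0.10. Targets of NRF2, the regulator of antioxidant genes, were higher as a list, with 2 of 31 risen, none fallen and 29 not called, and 3 higher adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.479 with an estimated correlation). The call was lost without untreated wild-type array 1 (0.0543) and after a further quantile normalization (0.0540). These were Srxn1, which repairs oxidised peroxiredoxins (0.76 ± 0.19), and Cbr3, a carbonyl reductase (0.67 ± 0.14).

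Of 19 measured genes of cholesterol synthesis in wild-type liver 9 fell, none rose and 10 were not called, and 11 fell when adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.479 with an estimated correlation). Pmvk and Mvk, kinases of the mevalonate pathway, fell by 1.31 ± 0.20 and 1.04 ± 0.19, Fdft1, which makes squalene, by 1.00 ± 0.18 and Hmgcs1, which makes the precursor HMG-CoA, by 0.69 ± 0.11. Of the 3 other probe sets of Fdft1, 1 had the same sign and none was called against it. In fatty acid and triglyceride synthesis 3 of 24 genes fell, none rose and 21 were not called, with 4 lower adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.479 with an estimated correlation). They were Scd2, a fatty acid desaturase (-1.42 ± 0.14), Srebf1, the regulator of lipid synthesis genes (-1.42 ± 0.27), and Acss2, which makes acetyl-CoA (-0.61 ± 0.13). Interferon response genes were lower as a list, with 6 of 28 fallen, none risen and 22 not called, and 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.479 with an estimated correlation). Rsad2, an antiviral enzyme, fell by 1.32 ± 0.27 and Ifit1, which binds viral RNA, by 0.81 ± 0.18. Of the 2 other probe sets of Rsad2, 1 had the opposite sign and was not called. Of 28 cell cycle genes 1 fell, none rose and 27 were not called, with 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.95e-06, adjusted p = 0.479 with an estimated correlation). The gene was Tk1, a thymidine kinase of S phase (-1.76 ± 0.26). The mean change of the cell cycle list in the MMS response in wild-type liver was -0.82, and -0.54 without untreated wild-type array 3.

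Markers of 3 other cell types were called lower as lists in treated wild-type liver. All 18 endothelial markers had negative values, of which 6 fell, none rose and 12 were not called, with 8 lower adjusted over the list alone (camera adjusted p = 1.8e-05, adjusted p = 0.470 with an estimated correlation). They included the growth factor receptors Tek (-0.73 ± 0.13) and Kdr (-0.65 ± 0.13). Of 17 stellate cell and fibroblast markers 4 fell, none rose and 13 were not called, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00358, adjusted p = 0.479 with an estimated correlation). They included the collagen genes Col1a1 (-2.49 ± 0.34), Col3a1 (-1.49 ± 0.25) and Col1a2 (-1.48 ± 0.27). Of 21 lymphocyte markers 2 fell, none rose and 19 were not called, with 7 lower adjusted over the list alone (camera adjusted p = 0.00458, adjusted p = 0.470 with an estimated correlation). They were the B cell receptor subunit Cd79b (-1.36 ± 0.21) and the T cell receptor subunit Cd3e (-1.08 ± 0.28). The macrophage list was not called (camera adjusted p = 0.224), with Adgre1, which encodes the marker F4/80, lower (-0.98 ± 0.15) and the scavenger receptor Marco higher (1.29 ± 0.34). DNA damage lists were not called either. Of 28 p53 targets 1 rose, 3 fell and 24 were not called, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.422). Aen, a nuclease of apoptosis, rose by 0.80 ± 0.17, and Cdkn1a, the cell cycle inhibitor p21, fell by 1.95 ± 0.51. Of 20 genes of base excision repair and direct reversal 1 rose, none fell and 19 were not called, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.642). It was Ung, the uracil glycosylase (1.77 ± 0.28).

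The largest single changes in wild-type liver included genes of the circadian clock. Dbp, a clock output transcription factor, rose by 4.33 ± 0.47 (20.2-fold, adjusted p = 0.00214) and Nr1d1, a clock repressor, by 3.19 ± 0.33 (9.16-fold), while Npas2 and Arntl, partners in the activating clock complex, fell (-4.96 ± 0.73 and -3.18 ± 0.65). The other probe set of Npas2 had the opposite sign and was not called. In the clock list 5 of 19 genes rose, 3 fell and 11 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.479 with an estimated correlation). The call was not kept after quantile normalization (0.0749) or median centring (0.171). A clock score was formed from log2 values centred on each gene's mean but not scaled, so genes with large changes weigh most. This score, the mean of evening-peaking genes minus that of dawn-peaking genes, was -2.85 to -2.33 in untreated wild-type arrays and 1.18 to 1.39 in treated ones. Also among the 10 largest increases were Rgs16, a regulator of G protein signalling (18.3-fold, 95% interval 2.33 to 6.06 in log2), Bhlha15, a transcription factor of secretory cells (4.17 ± 0.88), Sphk2, a sphingosine kinase (95% interval 3.05 to 4.95 in log2). Others were Gnat1, a transducin subunit (3.12 ± 0.35), Socs3, an inhibitor of cytokine signalling (3.07 ± 0.70), and 2010003K11Rik (3.02 ± 0.42). Sphk2 lies beside Dbp in the genome, and its other probe set had the opposite sign and was not called. The largest decreases also included Pls1, an actin-bundling protein (8.02-fold, adjusted p = 0.00524), Grk5, a receptor kinase (-2.75 ± 0.43), Gpm6a, a membrane glycoprotein (-2.54 ± 0.33). They further included the histocompatibility gene H2-Q2 (-2.47 ± 0.47), Slc34a2, a phosphate transporter (-2.41 ± 0.33), Tff3, a trefoil factor (-2.40 ± 0.48), and Hoxc8, a homeobox gene (-2.30 ± 0.53). Pdk4, which limits glucose oxidation (-1.77 ± 0.19), Ppargc1a, a coactivator of fasting genes (-1.62 ± 0.32), and G6pc, the glucose-releasing phosphatase (-1.38 ± 0.34), also fell. Their lists were not called (camera adjusted p = 0.209 for fatty acid oxidation and 0.224 for gluconeogenesis).

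In total 1458 of 22626 probe sets passed the threshold in wild-type liver, 451 higher and 1007 lower, and 509 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 5245 (23.2%), and 31.8% of probe sets had groups that did not overlap, against 10% by chance. The share called higher was 30.9% as deposited, 53.7% after a further quantile normalization and 72.8% after centring each array on its median. Centring moved the median change of all probe sets from -0.05 to 0.14, so the balance of direction was not settled. No called list changed the sign of its mean under either scaling. The count fell to 274, 877 and 346 without untreated wild-type arrays 1, 2 and 3, and to 779, 714 and 717 without treated wild-type arrays 1, 2 and 3. It was 4873 with array weights, 2222 without both knock-out arrays numbered 3, 2288 with the ratio of 5' to 3' signal of the actin and Gapdh control probe sets as a covariate, and 14 with the clock score as a covariate, where 0 of the 117 named genes kept their call. The changes of those genes kept their sign in 111 and stayed at a median of 0.951 of their size (quartiles 0.618 and 1.26), with Creld2 at 2.44 and Nupr1 at 2.15 in the MMS response in wild-type liver with the clock score as covariate. Wild-type groups do not overlap in the score, so its slope came from spread within groups, widest in untreated knock-out liver (-1.01, -1.34 and 1.99). These adjusted sizes therefore decide nothing about time of day. That covariate also ended the calls of the endothelial (0.144, mean -0.40 against -0.45), stellate (0.420, -0.58 against -0.67) and lymphocyte lists (0.555, -0.46 against -0.51), whose means stayed near their size. It ended those of the interferon (0.208, -0.04 against -0.38), NRF2 (0.144, -0.0111 against 0.12), ribosome biogenesis (0.900, -0.15 against 0.36) and clock lists (0.991, -0.43 against 0.36), whose means did not. Of the 117 named genes called, 36 kept their call without untreated wild-type array 1, 65 without array 2 and 36 without array 3, and 63, 56 and 57 without treated wild-type arrays 1, 2 and 3.

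**Figure D1:**
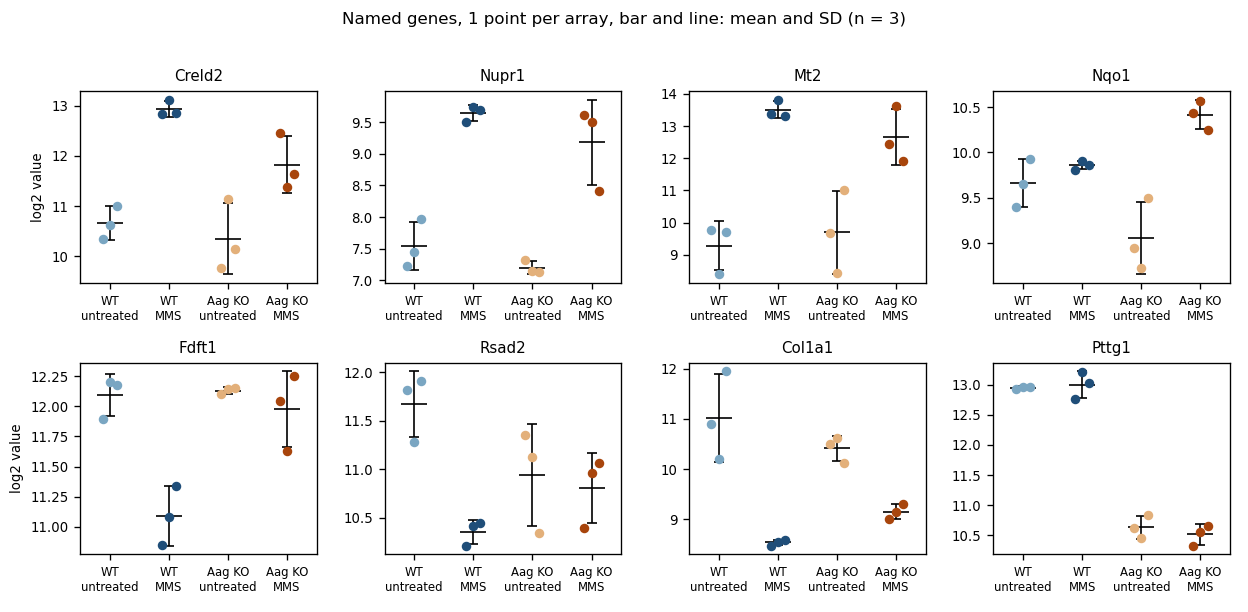
Deposited log2 values of 8 named genes in each of the 12 arrays (vertical axis), by genotype and treatment (horizontal axis), with 1 point per array and the mean and SD of each group of 3. Creld2, Nupr1, Mt2, Fdft1, Rsad2 and Col1a1 changed after MMS in wild-type liver, Nupr1, Mt2 and Nqo1 rose in knock-out liver, and Pttg1 was lower in all knock-out arrays.

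In Aag knock-out liver the same comparison asked which transcripts differ after MMS when Aag is absent. Mt2 rose by 2.97 ± 0.62 (7.86-fold, adjusted p = 0.0472), Nupr1 by 1.98 ± 0.29 (3.95-fold), Nqo1, an antioxidant quinone reductase, by 1.36 ± 0.20 (2.57-fold) and Manf by 1.34 ± 0.27 (2.52-fold). Ribosome biogenesis genes were higher as a list, with 2 of 26 risen, none fallen and 24 not called, and 19 higher adjusted over the list alone (camera adjusted p = 1.9e-09, adjusted p = 0.582 with an estimated correlation). These were Gar1, a component of small nucleolar ribonucleoproteins (1.31 ± 0.25), and Pes1, a factor of large subunit assembly (0.86 ± 0.19), whose other probe set had the opposite sign and was not called. In the proteasome list 0 of 31 genes passed the threshold in limma, while 5 were higher adjusted over the list alone and 26 were positive (camera adjusted p = 1.7e-05, adjusted p = 0.582 with an estimated correlation). Its member with the smallest p, Psmd4, stood at 0.91 ± 0.21 (adjusted p = 0.0566). Chaperone and degradation genes of the unfolded protein response were higher as a list, with 2 of 35 risen, none fallen and 33 not called, and 8 higher adjusted over the list alone (camera adjusted p = 0.00211, adjusted p = 0.838 with an estimated correlation). Besides Manf this was Dnajb11, a cofactor of Hspa5 (0.73 ± 0.16), whereas Creld2 stood at 1.48 ± 0.35 (adjusted p = 0.0587). The list mean relative to all 12 arrays was 0.23, -0.17 and -0.06 in treated knock-out arrays 1, 2 and 3, and the mean log2 value of markers of pancreatic acinar cells, a secretory cell type, was 9.49, 6.57 and 6.39. The mean change of the unfolded protein response list, 0.31, was 0.20 without treated knock-out array 1, where its call was kept. Of 32 PERK and ATF4 targets 1 rose, Nupr1, none fell and 31 were not called, with 6 higher adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.582 with an estimated correlation). Of 31 NRF2 targets 3 rose, none fell and 28 were not called, with 7 higher adjusted over the list alone (camera adjusted p = 0.0319, adjusted p = 0.582 with an estimated correlation). They were Nqo1, Srxn1 (1.18 ± 0.19) and Cbr3 (0.81 ± 0.14). Without untreated knock-out array 3 these last 3 lists had adjusted p values of 0.0894, 0.0787 and 0.106, and without treated knock-out array 3 the PERK and ATF4 list had 0.0836 and the NRF2 list 0.0577. The NRF2 list had 0.0540 with the 5' to 3' signal as a covariate.

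Of 28 acute phase genes in knock-out liver 1 rose, Mt2, none fell and 27 were not called, with 3 higher adjusted over the list alone (camera adjusted p = 0.0359, adjusted p = 0.838 with an estimated correlation). That list had 0.281 without untreated knock-out array 3, 0.601 without treated knock-out array 2, and 0.0713 and 0.0594 without treated wild-type arrays 1 and 2. It had 0.0545 after quantile normalization and 0.390 with the 5' to 3' signal as a covariate, which took its mean change from 0.37 to 0.12. Of 28 interferon response genes 1 rose, Oasl1, an antiviral protein (0.91 ± 0.15), none fell and 27 were not called, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.838 with an estimated correlation). It had 0.599, 0.138 and 0.0836 without untreated knock-out array 3 and treated knock-out arrays 2 and 3, and 0.216 after quantile normalization. The p53 target list was not called (2 of 28 risen, none fallen, 26 not called, 2 higher adjusted over the list alone, camera adjusted p = 0.877), and the risen genes were Aen (0.93 ± 0.17) and Mdm2, the ubiquitin ligase of p53 (0.87 ± 0.18). Base excision repair had 0 of 20 genes past the threshold in limma and 0 adjusted over the list alone (camera adjusted p = 0.367), with Ung at 0.95 ± 0.28 (adjusted p = 0.0842). Xpa, a factor of nucleotide excision repair, rose by 1.21 ± 0.25, while its 2 other probe sets had the opposite sign and were not called. Markers of pancreatic acinar cells, which make digestive enzymes, were higher as a list with 0 of 13 members past the threshold in limma, 1 higher adjusted over the list alone and 13 positive (camera adjusted p = 0.0269, adjusted p = 0.838 with an estimated correlation). Reg1, a secreted acinar protein, stood at 4.15 ± 0.99 (adjusted p = 0.0581). Without treated knock-out array 1 the acinar list had an adjusted p of 0.946, without untreated knock-out array 3 it had 0.0787, and with the 5' to 3' covariate 0.140.

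The other large increases in knock-out liver were Krt19, a keratin of bile duct cells (1.90 ± 0.40), Tgm1, a transglutaminase (1.88 ± 0.38), Cdk2ap2, a protein associated with CDK2 (1.76 ± 0.35). They also included the histocompatibility gene H2-Bl (2.84-fold, adjusted p = 0.0245), Prmt5, an arginine methyltransferase (1.36 ± 0.26), and Tssc4, a factor of spliceosome assembly (1.34 ± 0.18). The largest decreases included Gpm6a (-1.91 ± 0.33), Clec2h, a lectin (-1.80 ± 0.32), Slc25a30, a mitochondrial carrier (-1.80 ± 0.38), Robo1, a guidance receptor (-1.74 ± 0.28), Cdkal1, a tRNA-modifying enzyme (-1.70 ± 0.29). Others that fell were Exoc4, a subunit of the exocyst (-1.53 ± 0.17), Ccn4, a matrix protein (-1.47 ± 0.20), Spred2, an inhibitor of Ras signalling (-1.35 ± 0.24), and Neurod2, a neuronal transcription factor (-1.33 ± 0.28). In total 341 probe sets passed the threshold, 169 higher and 172 lower (49.6% higher), 121 of them differing at least 2-fold. At an unadjusted p under 0.05 there were 5610 (24.8%), and 26.7% of probe sets had groups that did not overlap, against 10% by chance. Median centring moved the median change of all probe sets from -0.06 to -0.13. The mean difference of 5' and 3' signal at the actin and Gapdh controls was -1.61 and -1.51 in treated knock-out arrays 1 and 2 but -2.46 in array 3, against -2.66 to -2.33 in the untreated knock-out arrays.

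The count in knock-out liver rested on single arrays. It was 0, 1 and 812 without untreated knock-out arrays 1, 2 and 3, and 0, 0 and 3264 without treated knock-out arrays 1, 2 and 3. It was 30, 13 and 35 without untreated wild-type arrays 1, 2 and 3, and 676, 611 and 69 without treated wild-type arrays 1, 2 and 3, which enter through the shared spread. Of the 37 named genes called, 0 kept their call without untreated knock-out arrays 1 or 2 or treated knock-out arrays 1 or 2, 31 without untreated knock-out array 3 and 37 without treated knock-out array 3. There were 7, 2 and 8 that kept it without untreated wild-type arrays 1, 2 and 3, and 12 without treated wild-type array 3. With both knock-out arrays numbered 3 left out there were 3326 probe sets, and all 37 named genes kept their call. Without treated array 3, the 5' to 3' signal of treated knock-out arrays (-1.61 and -1.51) lay outside the untreated knock-out range (-2.66 to -2.33). Treatment and that signal could then not be told apart in these larger counts. The count was 5790 with array weights, 0 with the 5' to 3' signal as a covariate and 1 with the clock score as a covariate, where 0 of the named genes kept their call. All 37 kept their sign with either, at a median of 0.741 of their size with the former (quartiles 0.610 and 0.928) and 0.938 with the latter. The count was 0 with the spread taken from the knock-out groups alone, 198 without moderation, 1029 with a trended robust variance, and 799, 1672 and 533 with the lowest 20% of probe sets removed, the lower-signal probe sets removed and quantile normalization. With the animal number as a block it was 19, and 5 of the 37 named genes kept their call.

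The responses of the genotypes were set side by side to ask how far they share genes. Of the 1458 probe sets called in wild type 1150 (78.9%) had the same sign in the knock-out. Among called genes, Mt2, Nupr1, Manf, Dnajb11, Srxn1, Cbr3 and Aen rose in both genotypes, and Gpm6a and the endothelial marker Oit3 fell in both. Per direction, 33 probe sets were higher in both genotypes, where independent lists would share 3.37, and 81 were lower in both, where they would share 7.66. Oasl1 was among the 5 called in opposite directions. Across all 22626 probe sets the responses correlated at r = 0.314 (Spearman 0.241), and at r = 0.657 across the probe sets called in wild type. Genes are not independent replicates, and the comparisons share no arrays. The correlation ran from 0.208 to 0.413 as single arrays were left out.

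**Figure D2:**
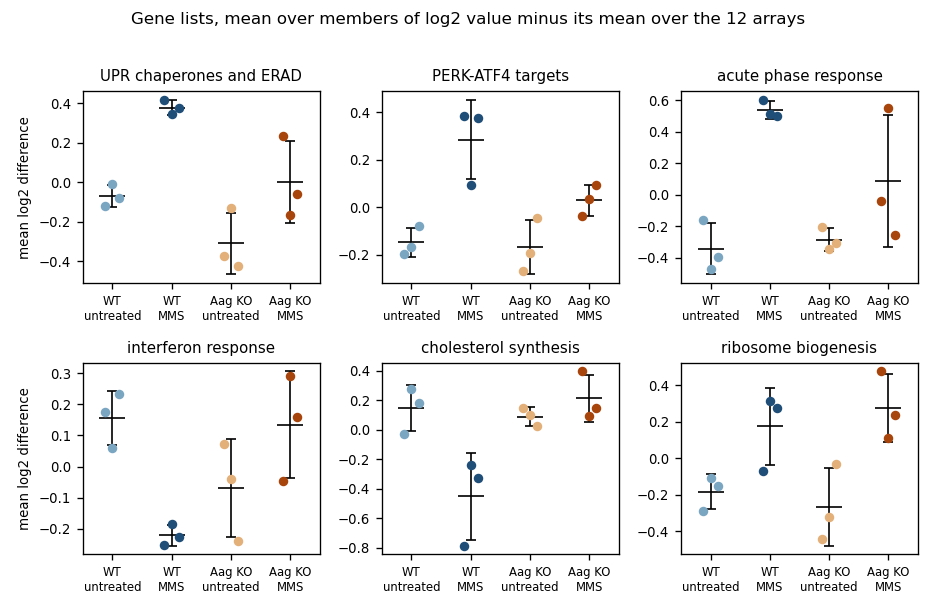
Mean over the members of 6 gene lists of the log2 value minus each gene's mean over the 12 arrays (vertical axis), by genotype and treatment (horizontal axis), with 1 point per array and the mean and SD of each group of 3. The cholesterol synthesis list lies at -0.78 to -0.24 in the treated wild-type arrays and at 0.09 to 0.40 in the treated knock-out arrays, where the unfolded protein response list spans -0.17 to 0.23.

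Without treatment, the genotypes were compared to find what loss of Aag alone is associated with. The genes past the threshold were Pttg1 (3 probe sets), clock genes, Sphk2, Rfxank and Akr1d1. Pttg1, securin, which blocks the separation of sister chromatids until anaphase, was 4.99-fold lower in the knock-out (-2.32 ± 0.15, adjusted p = 9.3e-05). Nr1d1 was 12.1-fold higher (3.60 ± 0.33, adjusted p = 0.00158), and Dbp (3.36 ± 0.47), Sphk2 (3.16 ± 0.43) and Nr1d2, the paralogue of Nr1d1 (1.49 ± 0.18), were also higher. The other probe set of Sphk2 had the opposite sign and was not called. Rfxank, a subunit of the factor that drives class II histocompatibility genes, was lower (-1.47 ± 0.20). Akr1d1, a reductase of bile acid synthesis, was lower at a probe set that does not represent the gene in the lists (adjusted p = 0.0282). In the clock list 3 of 19 genes were higher, none lower and 16 not called, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0420, adjusted p = 0.660 with an estimated correlation). The clock score was -1.01, -1.34 and 1.99 in untreated knock-out arrays 1, 2 and 3, above the range of -2.85 to -2.33 of untreated wild-type arrays, and array 3 lay above the treated arrays. Of 28 cell cycle genes 0 passed the threshold in limma, while 4 were lower adjusted over the list alone and 25 were not positive (camera adjusted p = 1.2e-08, adjusted p = 0.660 with an estimated correlation). Mcm3 and Mcm5, subunits of the replicative helicase, stood at -1.02 ± 0.30 and -1.35 ± 0.41. The mean of the cell cycle list, relative to all 12 arrays, was 0.57, -0.11 and 1.09 in untreated wild-type arrays 1, 2 and 3 and -0.38 to 0.10 in all others. Its genotype difference without treatment, -0.59, was -0.31 without untreated wild-type array 3 and -0.91 without untreated wild-type array 2.

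In the unfolded protein response list 0 of 35 genes passed the threshold in limma between untreated genotypes, and 2 were lower adjusted over the list alone (camera adjusted p = 0.00565 for lower, adjusted p = 0.660 with an estimated correlation). The disulfide isomerase Pdia4 stood at -1.43 ± 0.40. The list had 0.0897 without untreated wild-type array 2, 0.289 without untreated knock-out array 3 and 0.0551 among higher-signal probe sets. Of 28 interferon genes 0 passed the threshold and 1 was lower adjusted over the list alone (camera adjusted p = 0.00492, adjusted p = 0.660 with an estimated correlation). Oasl1 stood at -0.69 ± 0.15, and the list had 0.376 without untreated knock-out array 3. The NF-kB and cytokine list was higher with 0 of 25 genes past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00492, adjusted p = 0.660 with an estimated correlation), with the chemokine Ccl20 at 0.53 ± 0.14. The lists of fatty acid synthesis (1 of 24 lower adjusted over the list alone), heat shock (0 of 21), gluconeogenesis (1 of 17) and stellate cells (0 of 17) were called lower, and that of lymphocytes (0 of 21) higher, with 0 members past the threshold in limma in each. Their p values are given in the same order (camera adjusted p = 0.00565, 0.00565, 0.0335, 0.0420 and 0.0335, adjusted p = 0.660 with an estimated correlation for each). Scd2 stood at -0.66 ± 0.14, the heat shock protein Hspa4l at -0.57 ± 0.17, the aminotransferase Tat at -0.75 ± 0.19, the smooth muscle protein Tagln at -0.82 ± 0.27 and the interleukin receptor Il7r at 0.34 ± 0.14. Fatty acid synthesis had 0.0579 and 0.0562 without untreated wild-type array 3 and untreated knock-out array 1, and heat shock had 0.0679, 0.177 and 0.0615 without untreated wild-type array 2 and untreated knock-out arrays 1 and 3. Gluconeogenesis had 0.160, 0.0563 and 0.206 without untreated wild-type array 3 and untreated knock-out arrays 1 and 2, and lymphocytes had 0.133 and 0.497 without untreated wild-type array 2 and untreated knock-out array 1. The stellate list had 0.701 and 0.315 without untreated wild-type array 3 and untreated knock-out array 3, 0.0590 and 0.0504 without treated wild-type arrays 1 and 3, and 0.0527 without treated knock-out array 1 or 2. The clock list had 0.0937, 0.0778 and 0.376 without untreated wild-type arrays 1 and 2 and untreated knock-out array 3, and 0.0591, 0.0696, 0.0575, 0.0527, 0.0745 and 0.0506 without treated wild-type arrays 1, 2 and 3 and treated knock-out arrays 1, 2 and 3. Median centring ended the clock call (0.116). The clock score as a covariate ended it (0.900, mean -0.18 against 0.32), along with those of the unfolded protein response (0.856, -0.16 against -0.24), interferon (0.345, -0.00963 against -0.22), heat shock (0.161, -0.29 against -0.23) and stellate lists (0.856, -0.22 against -0.28). The 5' to 3' covariate left the clock list at 0.0533 (mean 0.34) and the stellate list at 0.111 (mean -0.23). The stellate list had 0.0553 after quantile normalization, and the lymphocyte call was lost with median centring (0.0804) and quantile normalization (0.180). Of the 10 lists called between untreated genotypes, 3 kept their call among higher-signal probe sets. There were 5 that kept it with array weights, and 5 without both knock-out arrays numbered 3.

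In total 9 probe sets passed the threshold between untreated genotypes, 4 higher and 5 lower (44.4% higher), and 1620 (7.16%) had an unadjusted p under 0.05. The groups did not overlap in 18.3% of probe sets, against 10% by chance. Quantile normalization gave 4 higher of 7 (57.1%) and median centring 5 higher of 8 (62.5%). The count was 18 without untreated knock-out array 3, 14 without untreated wild-type array 2, 4 without untreated wild-type array 1 or 3, and 5 without untreated knock-out array 1, treated knock-out array 1 or 2, or treated wild-type array 1 or 3. Array weights gave 182, the fit without moderation 5 and the spread of the untreated groups alone 3. Of the 6 named genes, 2 kept their call without untreated wild-type array 1 or 3 or untreated knock-out array 1, 4 without untreated wild-type array 2 or treated knock-out array 3, and 3 without treated wild-type array 1, 2 or 3 or treated knock-out array 1 or 2. Untreated knock-out arrays 2 and 3 each left 5. Pttg1 and Nr1d1 kept their call with each array left out, and with the clock score as a covariate 1 of the 6 did, Pttg1. All 6 kept their sign with that covariate, with Nr1d1 at 3.26, Rfxank at -1.24, Nr1d2 at 1.17, Dbp at 1.72 and Sphk2 at 1.68. The untreated groups do not overlap in the score, so these sizes rest on its spread within groups. With the 5' to 3' signal as a covariate 4 kept their call, and Dbp (3.40) and Sphk2 (3.17) had an adjusted p of 0.12. Rfxank lost its call after quantile normalization (0.110) and median centring (0.0920), and stood at -0.88 (0.182) as the mean of its probe sets. Dbp and Sphk2 lost theirs with a trended robust variance (0.122 and 0.0711), Dbp and Nr1d2 with the mean of the probe sets (0.181 and 0.0575), and Nr1d2 without both knock-out arrays numbered 3 (0.0505).

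**Figure D3:**
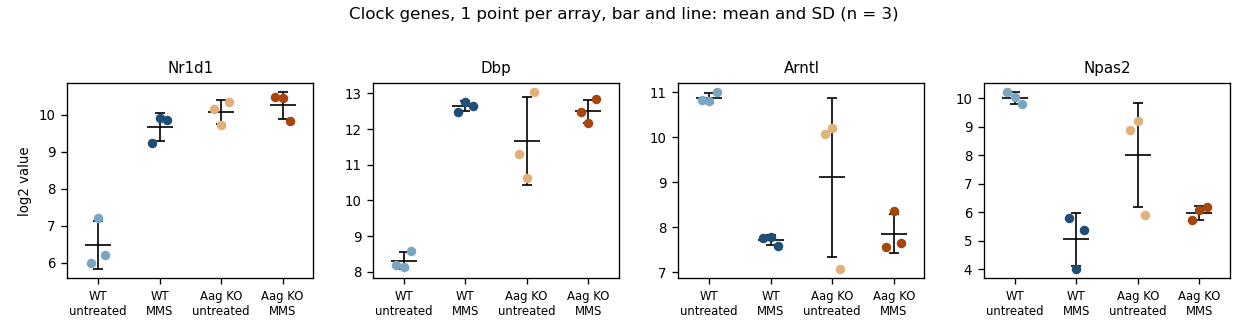
Deposited log2 values of 4 clock genes in each of the 12 arrays (vertical axis), by genotype and treatment (horizontal axis), with 1 point per array and the mean and SD of each group of 3. Nr1d1 lies at 5.99 to 7.22 in untreated wild-type arrays and at 9.24 or above elsewhere, and the lowest untreated knock-out point for Npas2 is array 3.

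After MMS, the genotypes were compared to ask how treated livers differ with and without Aag. Pttg1 was again lower in the knock-out, by 5.60-fold (-2.49 ± 0.15, adjusted p = 9.0e-05), and Ighv14-2, an immunoglobulin heavy chain segment, was higher (1.46 ± 0.19, adjusted p = 0.0448). All 19 genes of cholesterol synthesis had higher values in treated knock-out than in treated wild-type liver. None of the 19 passed the threshold in limma, and 16 were higher adjusted over the list alone (camera adjusted p = 8.9e-10, adjusted p = 0.477 with an estimated correlation). Sqle, which oxidises squalene, stood at 1.18 ± 0.25, Msmo1, a sterol demethylase, at 1.10 ± 0.20, Fdft1 at 0.88 ± 0.18 and Srebf2, the regulator of the pathway, at 0.80 ± 0.15. The unfolded protein response list was lower, with 0 of 35 past the threshold in limma and 2 lower adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.543 with an estimated correlation). Derl3, a component of endoplasmic reticulum degradation, stood at -2.80 ± 0.63, Sdf2l1, a chaperone cofactor, at -1.92 ± 0.34, Pdia4 at -1.41 ± 0.40 and Syvn1 at -1.08 ± 0.35. The PERK and ATF4 targets were also lower as a list, with 0 of 32 past the threshold in limma and 0 adjusted over the list alone (camera adjusted p = 0.00365, adjusted p = 0.360 with an estimated correlation). Mthfd2, an enzyme of mitochondrial folate metabolism, stood at -1.38 ± 0.44 and Atf3 at -0.68 ± 0.21. The call of this list ended with both knock-out arrays numbered 3 left out (0.0582).

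After MMS, acute phase genes were lower in the knock-out as a list, with 0 of 28 past the threshold in limma and 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.9e-05, adjusted p = 0.675 with an estimated correlation). Lcn2, a siderophore-binding protein, stood at -2.79 ± 0.49. Without treated knock-out array 3 this list had an adjusted p of 0.0835. Interferon genes were higher as a list, with 0 of 28 past the threshold and 5 higher adjusted over the list alone (camera adjusted p = 0.000218, adjusted p = 0.543 with an estimated correlation). Ifit3, Usp18 and Oasl1 stood at 0.94 ± 0.23, 0.89 ± 0.16 and 0.86 ± 0.15. Markers of lymphocytes (0 of 21 past the threshold, 2 higher adjusted over the list alone), macrophages (0 of 13, 7), stellate cells (0 of 17, 2 higher and 1 lower) and endothelium (0 of 18, 5) were higher as lists (camera adjusted p = 0.000494, 0.00148, 0.00541 and 0.0342, adjusted p = 0.360, 0.690, 0.675 and 0.690 with an estimated correlation). Gzma, a granzyme, stood at 1.82 ± 0.38, Cd79b at 1.14 ± 0.21, Adgre1 at 0.69 ± 0.15, Dcn, a matrix proteoglycan, at 0.66 ± 0.16 and Stab1, a scavenger receptor, at 0.53 ± 0.13. The endothelial list had 0.0527, 0.0952 and 0.103 without treated wild-type arrays 1 and 2 and treated knock-out array 2, and 0.117 after quantile normalization and 0.0514 after median centring. The 5' to 3' covariate left the endothelial and stellate lists at 0.0924 and 0.112 (means 0.19 against 0.24 and 0.21 against 0.40). The 5' to 3' signal difference was -2.6, -2.0 and -2.5 in treated wild-type arrays and -1.6, -1.5 and -2.5 in treated knock-out arrays.

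In total 4 probe sets passed the threshold between treated genotypes, 1 higher (25%) and 3 lower, all 3 of Pttg1, and 4156 (18.4%) had an unadjusted p under 0.05. The groups did not overlap in 17.6% of probe sets, against 10% by chance. Median centring gave 0 higher of 4 and moved the median of all probe sets from 0.02 to -0.14. The count was 1118 without treated knock-out array 3 and 6 without treated wild-type array 2, 1353 without both knock-out arrays numbered 3, 1482 with array weights, and 64 with a trended robust variance. It was 18 without the lowest 20% of probe sets, 200 without the lower-signal probe sets and 9 with 1 probe set per gene. Without treated knock-out array 3 the treated genotypes did not overlap in 5' to 3' signal, so genotype and that signal could not be told apart. Ighv14-2 lost its call without untreated wild-type array 3 (0.113), untreated knock-out arrays 1 (0.0855), 2 (0.0839) or 3 (0.0555), treated wild-type arrays 1 (0.179), 2 (0.0864) or 3 (0.0841), treated knock-out arrays 1 (0.0856) or 2 (0.0948), with median centring (0.0562), and with the 5' to 3' (0.0856) and clock covariates (0.0618). The animal number as a block also ended the call of Ighv14-2 (0.0999). Pttg1 kept its call in each of these fits.

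The difference of the MMS responses, knock-out minus wild type, asked directly whether the response depends on Aag. The genes with the smallest p were Irs1, an adaptor of insulin signalling (1.46 ± 0.18), Papln, a matrix protein (-1.48 ± 0.20), and Oasl1 (1.55 ± 0.21), each with an adjusted p of 0.0649. No probe set passed the threshold in limma, and 4009 (17.7%) had an unadjusted p under 0.05. The count was also 0 in the model without moderation, 20 with 1 probe set per gene, and 28 with a trended robust variance. It was 43 among higher-signal probe sets, 514 without both knock-out arrays numbered 3, 174 with the clock score as a covariate and 2344 with array weights. It was 158 without untreated knock-out array 3, 104 without treated knock-out array 3, 1 without treated knock-out array 2 and 2 without treated wild-type array 3. Without treated knock-out array 3 the treated knock-out arrays did not overlap the other groups in 5' to 3' signal. Cholesterol synthesis had a higher response in the knock-out in all 19 genes, with 0 past the threshold in limma and 8 higher adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.741 with an estimated correlation). Pmvk stood at 1.60 ± 0.28. Interferon genes (24 of 28 positive, 0 past the threshold, 8 higher adjusted over the list alone) and cell cycle genes (24 of 28 positive, 0 past the threshold, 2 higher) also had a higher response (camera adjusted p = 3.2e-05 and 0.000405, adjusted p = 0.741 with an estimated correlation for each). Ifit3 stood at 1.45 ± 0.32 and Tk1 at 1.69 ± 0.37. Stellate markers (14 of 17 positive, 0 past the threshold, 9 higher and 1 lower adjusted over the list alone), fatty acid synthesis (20 of 24, 0, 1 higher) and endothelial markers (14 of 18, 0, 0) had camera adjusted p values of 0.00234, 0.0296 and 0.0442 for a higher response (adjusted p = 0.741 with an estimated correlation for each). Dcn stood at 0.87 ± 0.22, Scd2 at 1.40 ± 0.19 and Kdr at 0.63 ± 0.19. Acute phase genes had a lower response (4 of 28 positive, 0 past the threshold in limma and 0 adjusted over the list alone, camera adjusted p = 0.000722, adjusted p = 0.741 with an estimated correlation). Socs3 stood at -2.77 ± 0.99 and Steap4, a metalloreductase, at -0.91 ± 0.24. The unfolded protein response list was not called in this test (mean difference -0.14, camera adjusted p = 0.181), nor were the PERK and ATF4 targets (-0.23, 0.0659), but both depended on the setting. The former had -0.25 (0.00484) without treated knock-out array 1, the array with the highest acinar markers, and -0.05 without treated knock-out array 2 (0.405) or untreated knock-out array 2 (0.570). It passed among higher-signal probe sets (0.00690) and with the clock score as a covariate (0.0407, -0.22). The latter passed without treated knock-out array 1 (0.0334), untreated wild-type array 3 (0.0353) or treated wild-type array 2 (0.0193). It also passed without the lowest 20% of probe sets (0.0150), among higher-signal probe sets (0.0148, -0.15) and after quantile normalization (0.0272). Median centring gave -0.40 and -0.49 (0.138 and 0.112), and 5' to 3' and clock covariates gave -0.14 and -0.11 for the latter.

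The calls of 3 of these lists depended on single arrays. The clock score as a covariate ended those of the interferon (0.239, mean 0.38 against 0.58), endothelial (0.373, 0.30 against 0.33) and stellate lists (0.115, 0.62 against 0.68). The 5' to 3' covariate ended those of the endothelial (0.108, 0.26) and stellate lists (0.0509, 0.44). The acute phase list had 0.0955 without treated knock-out array 3. Fatty acid synthesis had 0.0825, 0.0506, 0.0669 and 0.149 without untreated wild-type array 3, untreated knock-out array 1 and treated knock-out arrays 1 and 3. The endothelial list had 0.0567 and 0.0825 without untreated wild-type arrays 1 and 3, 0.0510 and 0.132 without untreated knock-out arrays 2 and 3, 0.0568 and 0.0672 without treated wild-type arrays 1 and 2, and 0.0868 without treated knock-out array 2. It had 0.144 after quantile normalization and 0.0713 after median centring. Among higher-signal probe sets fatty acid synthesis had 0.124 and the endothelial list 0.176. Of the 7 lists, 4 kept their call without both knock-out arrays numbered 3 and 5 with either filter on low values. With array weights, the animal number as a block or a trended robust variance 6 kept it in each case. Median centring moved the median of this difference over all probe sets from 0.05 to -0.21, and no called list changed the sign of its mean under either scaling.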

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

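The tests that weigh the clock genes and treated knock-out array 3 in this part were chosen after the results were seen, whereas the contrasts, gene lists, left-out arrays, array weights and other splits were fixed before. The difference of the MMS responses, knock-out minus wild type, was called by camera for 7 gene lists, which is what marked them here. The mean log2 differences of the response were -0.51 for acute phase genes (-0.34 without treated knock-out array 3), 0.58 for interferon response, 0.72 for cholesterol synthesis, 0.38 for fatty acid and triglyceride synthesis, 0.77 for cell cycle (0.48 without untreated wild-type array 3, where the list was highest), 0.33 for endothelial markers and 0.68 for stellate cell and fibroblast markers. When genotype labels were exchanged within each treatment, 59 of 100 splits, the real one included, called as many lists as the real 7, with up to 16, so chance was not excluded for the number of lists. The count of probe sets was 0 for the real labels and at most 2 for others, and all 100 splits reached the real count.

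Other splits of the 6 arrays in a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For probe sets the real and the highest other count were 1458 and 0 for the wild-type response, 341 and 0 for the knock-out response, and 9 and 3 between untreated genotypes, with 1 split as large in each, the real one. Between treated genotypes they were 4 and 875, with 2 splits as large. The split with 875 sets treated wild-type arrays 1 and 3 and treated knock-out array 3 against the other 3 treated arrays, so these arrays hold a structure other than genotype. It follows the 5' to 3' signal of the control probe sets, which was -2.6, -2.5 and -2.5 in the former and -2.0, -1.6 and -1.5 in the latter. For gene lists the real and the highest other counts were 15 and 15 (2 splits as large), 8 and 15 (4), 10 and 11 (3) and 9 and 9 (2) in the same order.

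Clock genes differed between groups in 14 of 15 genes in the direction of a later time of day in treated than untreated wild-type liver (exact sign test p = 0.000977), and in 15 of 15 in untreated knock-out against untreated wild-type liver (exact sign test p = 6.1e-05). The counts were 12 of 15 in the knock-out response (exact sign test p = 0.0352) and 10 of 15 between treated genotypes (exact sign test p = 0.302). Genes of the clock move together, so these p values overstate the evidence. A difference in the time of collection could produce this pattern, and the collection times are not given. MMS as the whole cause of the clock differences between groups was argued against by the 3 clock genes past the threshold between untreated genotypes. That comparison holds no treated arrays, so it does not decide whether MMS caused the clock changes of the wild-type response. Whether other genes of the wild-type response follow the time of day could not be told. Treated and untreated wild-type arrays do not overlap in the clock score. With it as a covariate 14 probe sets remained, and 111 of 117 named genes kept their sign at a median of 0.951 of their size. Those sizes do not decide the question either, since the slope came from spread within groups, mostly that of untreated knock-out arrays.

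Treated knock-out array 3 stood apart from the other treated knock-out arrays, in its closest array, its 5' to 3' signal and its lowest array weight (0.303). The mean of the female-biased liver gene list, relative to all arrays, was 0.35 in it, against -0.29 and -0.39 in the other 2. That mean was 0.74 and 1.04 in untreated wild-type and knock-out arrays 3, and 0.06 or lower in every remaining array. The male-biased list was -0.13 in treated knock-out array 3, against -0.04 and -0.13 in the other 2. The sex of the animals is not given in the labels and was not tested. As to mislabelling, treated knock-out array 3 had a long-gene score, described below, of -0.47, against a lowest untreated value of -0.04. The long-gene pattern was found on these same data with this array counted as treated, so this score alone does not rule out an untreated animal. The Mpg value of the array was 5.32 at the probe set that separates the genotypes, against a lowest wild-type value of 6.21. That probe set was picked because it separates all arrays by genotype, this one included, so this value alone does not rule out a wild-type animal. At the other Mpg probe set the value of this array, 8.18, lay within the wild-type range of 7.84 to 8.50. Whether the RNA quality of the other 2 treated knock-out arrays sets them apart could not be told, since 0 probe sets passed in the knock-out response with the 5' to 3' signal as a covariate, while all 37 named genes kept their sign at a median of 0.741 of their size. No biological explanation was tested.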

How the results depend on the processing

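Of 162 calls of named genes, 2 were kept under all 21 other settings (Pttg1 between untreated and between treated genotypes), and of 49 calls of gene lists 1 was kept under all 25 (PERK and ATF4 targets in wild-type liver). Counts below are in the order wild-type response, knock-out response, untreated genotypes, treated genotypes and difference of responses, where 1458, 341, 9, 4 and 0 probe sets and 15, 8, 10, 9 and 7 lists were called. The cause was not tested for any change below unless stated. Signal over background was not analysed here, so what weak signal limits was not measured. A pseudocount was not run: values are log2.

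With single arrays left out the counts ran from 274 to 1798, 0 to 3264, 4 to 18, 3 to 1118 and 0 to 158, and the lists from 14 to 18, 3 to 10, 6 to 12, 8 to 11 and 6 to 10. A group with an array left out keeps 2 arrays. The correlation of the responses ran from 0.208 to 0.413. Mpg ran from -1.23 to -0.91 without treatment and -1.40 to -1.13 after MMS at its first probe set (adjusted p = 0.0317 to 0.183 after MMS), and from -0.42 to -0.16 and -0.45 to -0.17 at its other one.

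Array weights gave 4873, 5790, 182, 1482 and 2344, with 4 lists in the knock-out response and 6 between untreated genotypes, and Mpg at -0.93 and -1.20 passed the threshold. The upper-signal filter gave 1672, 200 and 43 for the knock-out response, treated genotypes and difference, and the 20% filter 799 and 18 for the first 2 of these, where fewer probe sets were tested; each called 3 lists in the knock-out response. The trended robust variance gave 1029, 64 and 28, and Mpg at -1.24 after MMS passed. Quantile normalization gave 533 in the knock-out response. With 1 probe set per gene, fewer tests gave 9 between treated genotypes and 20 for the difference. The spread of the compared groups alone gave 0 in the knock-out response and 3 between untreated genotypes, and no moderation 198 and 5. An estimated correlation called 1, 0, 0, 0 and 0 lists, fry called 3, 0, 4 and 0 in all but the wild-type response, and the mean of a gene's probe sets gave 11 for the difference.

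Animal numbers are not known to pair the arrays. In deviations from the group means, same-numbered arrays of different groups correlated at -0.475 to 0.403, over 0.1 in 7 of 18 pairs. With the number as a block the knock-out response had 19 probe sets and the others 1370, 6, 3 and 0. Of the named genes called, 91 of 117 kept their call in the wild-type response and 5 of 37 in the knock-out response. Nr1d2 (0.0797), Rfxank (0.0887) and Ighv14-2 (0.0999) lost their genotype calls. In the same deviations, 8 of the 12 arrays had their best match outside their group in an array of their own number, a hint from the data and not the design.

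Chosen after seeing the data, leaving out both knock-out arrays numbered 3 gave 2222, 3326, 1353 and 514 in all but the untreated genotypes, 4 lists in the knock-out response and 4 for the difference, and Mpg at -1.17 after MMS passed. The remaining treated knock-out arrays do not overlap the other groups in 5' to 3' signal. The 5' to 3' covariate gave 2288 and 0 for the responses. The clock score, which wild-type groups do not share, gave 14, 1 and 174 for the responses and their difference. With it the camera test of the interferon list reversed direction in the wild-type response (mean -0.0378) and between untreated genotypes (mean -0.00963), without passing the threshold. In the wild-type response the changes also reversed, none past the threshold, for Rgs16 (-0.0577), Arntl (0.494), Trib3 (-0.314), Cdkn1a (0.0415), Cmpk2 (0.382) and Tef (-0.0366). The means of the ribosome biogenesis (-0.15), clock (-0.43) and NRF2 (-0.0111) lists in the wild-type response, and of the clock list between untreated genotypes (-0.18), changed sign too, without a change of the direction of the test.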

Other observations

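All tests in this part were chosen after the results were seen. Long genes were lower after MMS in both genotypes, a pattern found on these same data and so a hypothesis. Only genes above the median in mean signal were used, and long genes of lower signal were not examined. Among 167 such genes longer than 200 kb the median change was -0.35 in wild-type and -0.43 in knock-out liver, with 46 and 34 past the threshold, all lower, against medians of -0.03 and 0.12 among 2922 such genes shorter than 20 kb. Exoc4, Robo1 and Cdkal1, named above, are among the genes that fell in knock-out liver. Between untreated genotypes the median of the long genes was -0.05 and 0 passed the threshold in limma.

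The long-gene score of an array used the same higher-signal genes, relative to untreated wild type. The median of long minus that of short genes was taken within bands of mean signal, and averaged with the number of long genes as weight. The score was -0.04 to 0.07 in the untreated arrays, -0.44 to -0.33 in treated wild-type and -0.71 to -0.47 in treated knock-out arrays. With treatment exchanged within genotype the exact permutation p was 0.005 over 400 regroupings, which fits an effect of MMS, and no mechanism was tested. RNA quality was argued against as the whole cause, since the 3 treated arrays within the 5' to 3' range of the untreated ones had scores of -0.33 or lower. Within each genotype the treated arrays outside that range scored lowest (-0.44 in wild type, -0.71 and -0.60 in the knock-out). A part played by RNA quality therefore stayed open. In the knock-out, 62 markers of other cell types shorter than 100 kb had a median of -0.00144 (interval -0.25 to 0.20, which treats genes as independent). Medians were -0.25 for lymphocytes, -0.03 for endothelium, 0.23 for stellate cells and 0.34 for macrophages, against -0.43 for long genes. These values argued against a shared loss of these cell types there, while a loss of lymphocytes alone stayed open. In wild type a loss of other cell types stayed open (-0.38). Time of day could not be told from 1 untreated array with a high clock score (0.00981).

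Pttg1 lies on the chromosome of Mpg with 28 measured genes between them, and its 3 probe sets were all lower in the knock-out averaged over treatments (-2.60, -2.86 and -2.40). Of the 100 genes nearest Mpg 9% had an unadjusted p under 0.05 in that test, against 8.31% of all genes, and 1 passed the threshold, Pttg1. Farther away on the same chromosome, Nr1d1 also passed (2.09, limma adjusted p = 0.0110). The acinar genes Ctrb1, Cpa1 and Reg1, picked after their values were seen, were at 11.1, 9.81 and 9.85 in treated knock-out array 1, and Reg1 at 11 in array 2.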
